A study of Homo sapiens with 4 samples.

How the data were processed

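IMR-32, an established human neuroblastoma cell line, carried either a TFAP2B transgene (transcription factor AP-2 beta) or a GFP transgene as control. Total RNA was taken at day 2 and at day 7, which gave 4 arrays, 1 per transgene and day. Per the labels' protocols, RNA was isolated with TRIzol, its integrity was measured on a Bioanalyzer, and it was amplified and labelled with Cy3 using an Agilent kit for 1-colour arrays. Each array was a custom Agilent design, and the 4 arrays lay on a single slide, per the file headers. Slide was therefore the same for every sample and was not a batch. In slide order each TFAP2B array came directly before the GFP array of its day, so position on the slide went with both transgene and day.

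The deposited scanner files gave, per the file headers, spot intensity on a linear scale from Agilent Feature Extraction 11.5.1.1, with background subtracted and spatial trends removed by that software but no normalization between arrays. They also held flags for spots well above background, saturated spots and outlier spots. The authors' deposited normalized table held log2 values of the same 4 arrays, made with limma per the submitters' processing notes. Its sorted columns differed by at most 0.00124 and each had a median of 8.73, as quantile normalization gives. The background correction and the signal column behind it were not given in the sources used here. Each column correlated with the log2 intensity of its own array at 0.977 to 0.981 and with any other array at no more than 0.963, and all 43291 probe names matched. The table served as an alternative.

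From the scanner files, log2 of the processed signal was taken, and the 75th percentile of the array's own non-control probes was subtracted. Control spots and outlier-flagged spots (2 to 7 per array) were left out, and no probe was saturated. All differences are thus relative to the bulk of probes on an array, not amounts per cell. A probe well above background on both arrays of a comparison had a measured log2 difference. On 1 of the arrays only, it had a bound, taken against the lowest signal among probes well above background on the dim array, or against the probe's own signal there where that was higher. On neither, it had no value. A probe was counted as higher or lower at a difference of at least 2-fold.

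With 1 array per transgene and day, no per-day difference has a replicate check, and no p-value was computed for one. The only test the arrays allowed was a limma 3.58.1 fit (R 4.3.3) over all 4 arrays with day and transgene as factors, moderated variances, and Benjamini-Hochberg adjusted p under 0.05. It left 1 residual degree of freedom per probe, and moderation added 7.03 prior degrees of freedom estimated from all probes. The spread used for a probe was therefore mostly a value pooled over probes. The probe's own part of it was the change of the difference between days, which included any real time course. Nothing in the labels says that the 4 RNA samples came from repeated cultures, so its p-values describe these arrays. Probes well above background on both arrays of a transgene or of a day entered, 30047 in all. Some of these were below background on an array, where the fit used the signal as measured. On simulated data with the same number of probes and 200 changed ones, the fit recovered none of those changed 2-fold. It recovered 95.5% of those changed 4-fold and 100% of those changed 8-fold. False calls numbered 0, 17 and 21. On the arrays themselves 2030 probes were called, far more than 200, and the smallest called difference was 0.93. The adjusted p depends on how many probes change, so the simulation does not show what share of 2-fold changes the fit finds here.

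The scanner files carry no gene names. Of the 43291 probe IDs, 41341 were Agilent catalogue numbers and 1833 were UniGene-type IDs. A RefSeq accession stood in 13 IDs, and 8 of these matched the human RefSeq table used for names (assembly GRCh38.p14). A further 2 IDs named TERT. The file headers name build hg18, which differs from that of the table, so no coordinates are given. Before the data were examined it had been decided to represent each gene by its brightest probe, to name TFAP2B, MYCN and REST, and to name the 10 largest measured differences per direction and day, the 5 largest bounds per direction and day, the 10 largest per direction in the fit and the 5 largest per direction in each time comparison, among probes with a gene symbol. It had also been decided to set 27 gene lists (684 entries) against random lists. With so few symbols the probe became the unit, 8 of the named gene probes are reported and the others are not reported here, the lists were not evaluated, and TFAP2B, MYCN and REST could not be given values. For the same reason the transgene itself was not checked on the arrays. For the largest differences, 2 probe IDs per direction are printed from the fit.

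The alternatives were quantile normalization, scaling to each array's median, the authors' table, only probes above background on both arrays or on all 4, no filter on dim probes, an intensity trend or robust estimation in limma, and limma without the day factor. After the data were examined, normexp background correction (offset 50) was run on median spot and background signals, because the files have no mean signal column. Scaling to 6 Agilent E1A spike-in controls of middle brightness and the comparison of days in TFAP2B cells were also added then. Averaging over the probes of a gene was not run. Leaving out any array leaves no residual degrees of freedom, so no such fit was made. Figures were drawn with matplotlib 3.10.9.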

Results

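The series measured how gene expression differed between IMR-32 cells with a TFAP2B transgene and IMR-32 cells with a GFP transgene. IMR-32 is a human neuroblastoma cell line, and TFAP2B is a transcription factor of the AP-2 family, which the series' title links to differentiation of noradrenergic neurons. There were 4 arrays, 1 each for TFAP2B cells and GFP cells at day 2 and day 7. Each array measured 43284 to 43289 usable probes, of which 29463 to 30292 were well above background. The 75th percentile of signal ranged from 926 to 1325, a 1.43-fold range. Replicate spots of the same spike-in control on an array had a median SD of 0.041 to 0.061 on the log2 scale, which is spot error within an array and not the spread between cultures. The number of arrays limits the precision of every comparison below.

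At day 2, 1405 probes were at least 2-fold higher and 1028 at least 2-fold lower in TFAP2B cells than in GFP cells, out of 31030 probes with a value (7.84%). Of these, 378 were at least 4-fold higher and 258 at least 4-fold lower. A probe known here as UKv4_A_23_P145054 was 68.8-fold higher (log2 difference 6.10), and UKv4_A_23_P166360 was 88.4-fold lower (log2 difference -6.47). With the authors' table these differences were smaller, 4.63 and -4.68, and with normexp they were 5.43 and -4.56. The files do not pair these IDs with gene names. The day 2 signal of UKv4_A_23_P166360 in TFAP2B cells was 20.0, close to 18.6, the lowest well above background on that array. Its fold at day 2 thus rests on a signal near the detection limit. Among probes above background on only 1 of the 2 arrays, the largest bounds were at least 157-fold higher and at least 142-fold lower. Measured differences of all 28677 probes above background on both arrays had a median of 0.02 and an SD of 0.58.

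The 6 named genes measured on both arrays differed by less than 2-fold at day 2 when scaled to the 75th percentile. PSMB5, a catalytic subunit of the proteasome, was 1.42-fold higher in TFAP2B cells (log2 difference 0.50). UHRF1, which is needed to maintain DNA methylation through replication, differed by 0.25 on the log2 scale, and CTTN, which encodes the actin-binding protein cortactin, by 0.14. With spike-in scaling the differences for PSMB5, UHRF1 and CTTN turned to -0.59, -0.84 and -0.95. SKP2, the substrate-binding subunit of a ubiquitin ligase that targets the cell cycle inhibitor p27, differed by 0.0040, and WDR33, part of the mRNA polyadenylation machinery, by -0.11. The full-length probe for TERT, the catalytic subunit of telomerase, differed by -0.39. With spike-in scaling SKP2, WDR33 and this TERT probe passed 2-fold, at -1.09, -1.20 and -1.48. The truncated TERT probe was not well above background on any array. SLC26A2, a sulfate transporter, was well above background in TFAP2B cells at day 2 and on no other array, with a lower bound of 0.58 on its log2 difference at day 2, and of 0 with spike-in scaling.

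**Figure D1:**
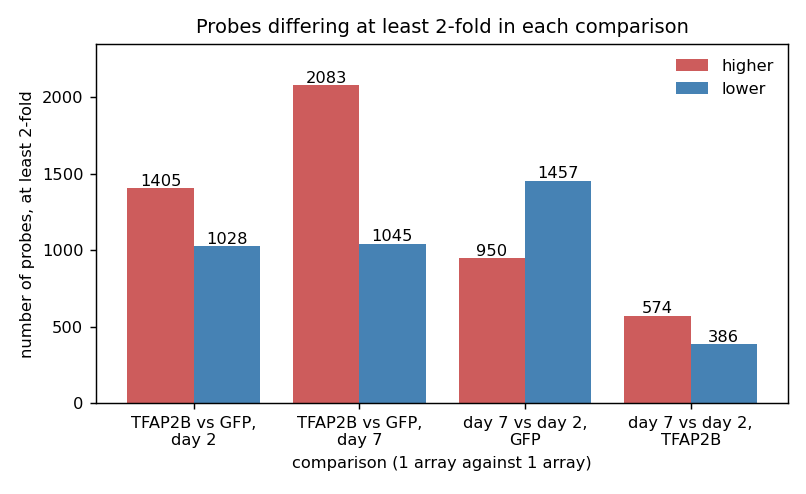
Number of probes (vertical axis) at least 2-fold higher (red) or lower (blue) in each of the 4 comparisons of 1 array with 1 array, bounds included. The TFAP2B cells had more probes higher than lower at both days, 1405 against 1028 and 2083 against 1045, and fewest probes changed from day 2 to day 7 in TFAP2B cells, 574 and 386. Scaling the arrays to their spike-in controls turned the direction of the first 3 comparisons.

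At day 7, 2083 probes were at least 2-fold higher and 1045 at least 2-fold lower in TFAP2B cells, out of 31226 with a value. At least 4-fold differences numbered 412 higher and 254 lower. UKv4_A_23_P145054 was again far higher, by 62.2-fold (log2 difference 5.96), and UKv4_A_23_P166360 was 64.0-fold lower (-6.00). The authors' table gave 4.61 and -4.46, and normexp 5.42 and -4.99. The largest bounds were at least 189-fold higher and at least 127-fold lower. Differences of the 28523 probes measured on both arrays had a median of -0.02 and an SD of 0.62.

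Of the genes named here, at day 7 SKP2 had the largest difference and was 1.86-fold lower in TFAP2B cells (log2 difference -0.89). UHRF1 was 1.37-fold higher (0.45) and PSMB5 1.24-fold higher (0.31), but with spike-in scaling their differences were -0.91 and -1.05. Differences for WDR33, the full-length TERT probe and CTTN were 0.086, 0.067 and 0.054, and changed sign under at least 1 other scaling of the arrays. With spike-in scaling these 3 were -1.27, -1.29 and -1.31, and SKP2 was -2.25. Counts at either day moved by over 1.5 times with the authors' table, which gave 1306 probes at day 2 and 1577 at day 7, and with other settings described further on. Scaling to spike-in controls turned the balance, to 338 higher and 17690 lower at day 2 and 222 higher and 23941 lower at day 7.

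The day 2 and day 7 differences, which share no array, were then compared. Of 29974 probes with a value at both days, 758 were at least 2-fold higher in TFAP2B cells at both days, 9.32 times the 81.3 of independent lists. At least 2-fold lower at both days were 504 probes, 17.2 times the 29.3 of independent lists. The authors' table gave 408 and 306, normexp 441 and 286, and spike-in scaling turned the balance to 140 and 14518. Opposite 2-fold differences were found for 11 probes higher at day 2 and lower at day 7, and for 30 lower at day 2 and higher at day 7, where independent lists would give 40.6 and 58.6. Across the 27889 probes above background on all 4 arrays, the 2 sets of differences had a Pearson correlation of 0.58 and a Spearman correlation of 0.38. These are correlations across probes, which are not independent replicates. Of 1630 probes that differed at least 2-fold at day 2, 90.7% had the same sign at day 7. Of the variation between the 4 arrays, 56.4% went with the transgene, 28.7% with the day and 14.8% with a change of the transgene difference between days.

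**Figure D2:**
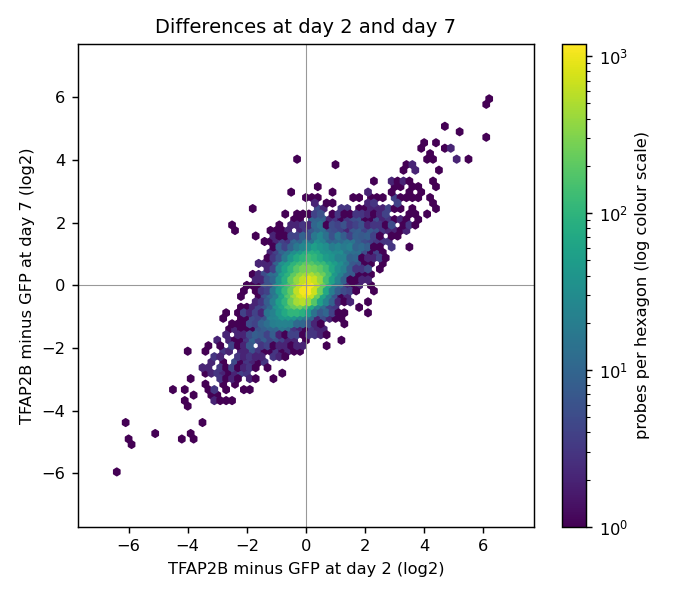
Log2 difference between TFAP2B and GFP cells at day 2 (horizontal axis) and at day 7 (vertical axis) for the 27889 probes above background on all 4 arrays, as hexagons coloured by the number of probes on a log scale. Large differences lie along the diagonal, from about the lowest day 2 value of -6.47 to the highest day 7 value of 5.96, and the Pearson correlation was 0.58.

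In the limma fit over both days, 2030 of 30047 probes differed between TFAP2B and GFP cells at adjusted p under 0.05, with 1142 higher and 888 lower. All 2030 had the same sign at both days, and their median difference was 1.62 in size. The shared sign is no separate support, since the fit's spread includes the change between days and opposite signs could not pass. UKv4_A_23_P145054 was higher in TFAP2B cells by 6.03 ± 0.23 (SE, adjusted p = 1.44e-05) and UKv4_A_23_P408376 by 5.92 ± 0.23 (adjusted p = 1.44e-05). Such SEs rest mostly on the spread pooled over probes, and the median SE of all probes tested was 0.23. UKv4_A_23_P166360 was lower, with a difference of -6.23 ± 0.24 (adjusted p = 1.44e-05), as was UKv4_A_23_P321501, with -5.50 ± 0.29 (adjusted p = 3.77e-05). With the authors' table these differences were smaller, in the same order 4.62, 4.43, -4.57 and -4.77. Each printed probe had its sign on both days, which was also a condition for printing it. Of the 2030, 1935 differed by at least 2-fold, and the smallest called difference was 0.93. Because the pooled spread keeps small differences from being called, the share past 2-fold follows in part from the fit, as does the median size. These sizes, and the median of 1.62, take signals below background as measured and not as bounds. Some of the 1935 were dim on both TFAP2B arrays and had bounds under 2-fold at both days. For others dim there, the bounds passed 2-fold. How many of the 1935 lack a 2-fold difference by their bounds was not counted. Without the day factor 814 probes were called, with arrays scaled to their medians 3166, and with spike-in scaling 446 higher and 26799 lower.

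None of the 6 named genes tested passed, and SLC26A2 was not tested. In limma, PSMB5 differed by 0.41 ± 0.23 (adjusted p = 0.423), UHRF1 by 0.35 ± 0.23 (adjusted p = 0.506) and SKP2 by -0.44 ± 0.28 (adjusted p = 0.481). For CTTN, WDR33 and the full-length TERT probe the limma differences were 0.10, -0.01 and -0.16, with adjusted p of 0.895, 0.991 and 0.822. These 6 differences, from -0.44 to 0.41, were all smaller in size than 0.93, the smallest called. At such sizes the spread pooled over probes kept a probe from being called, however well its days matched. Not passing therefore does not show that these genes were unchanged. With spike-in scaling all 6 were called as lower in TFAP2B cells. An unadjusted p under 0.05 was reached by 5468 probes in all, against 1502 by chance.

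Some probes were above background with 1 transgene alone. Both TFAP2B arrays and no GFP array were well above background for 276 probes, of which 119 were at least 2-fold higher and 20 at least 8-fold higher at both days by their bounds. The reverse held for 463 probes, with 84 at least 2-fold lower and 15 at least 8-fold lower in TFAP2B cells at both days. The flag limit differed between arrays. At day 7 the lowest signal well above background was 26.7 in TFAP2B cells and 22.7 in GFP cells, against 75th percentiles of 1184 and 1325. At day 2 it was 18.6 and 22.8, against 926 and 1175. The counts of 276 and 463 may thus reflect the flags as well as expression. By comparison, 180 probes were above background on both day 2 arrays alone and 146 on both day 7 arrays alone.

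The change with time in the GFP cells gives the background against which the TFAP2B cells can be set. In GFP cells 950 probes were at least 2-fold higher and 1457 at least 2-fold lower at day 7 than at day 2, 7.71% of 31236. TFAP2B cells had 574 higher and 386 lower, 3.14% of 30609, so that GFP cells changed at 2.51 times as many probes. That ratio ran from 1.08 with spike-in scaling to 4.12 with normexp, and the TFAP2B counts turned to 428 higher and 486 lower with median scaling and to 78 and 167 with normexp. The SD of the differences was 0.54 in GFP cells and 0.39 in TFAP2B cells, and the arrays of the 2 days correlated at 0.982 and 0.991. UHRF1 was lower at day 7 in both, 2.35-fold in GFP cells (log2 difference -1.23) and 2.04-fold in TFAP2B cells (-1.03). With spike-in scaling these turned positive, to 0.38 and 0.32. PSMB5 differed by -0.55 in GFP cells and -0.74 in TFAP2B cells, and by 1.06 and 0.60 with spike-in scaling. In the limma fit the day factor was called for 65 probes, and 3900 had an unadjusted p under 0.05.

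Among the 27889 probes above background on all 4 arrays, the difference between TFAP2B and GFP cells was at least 2-fold higher at day 7 than at day 2 for 1313 probes and at least 2-fold lower for 500. For the 1313, the median change from day 2 to day 7 was -0.98 in GFP cells and 0.31 in TFAP2B cells, and the GFP value moved more for 1006 (76.6%). For the 500, the medians were 0.94 in GFP cells and -0.29 in TFAP2B cells, and the GFP value moved more for 355 (71.0%). Both sets were chosen on the TFAP2B change minus the GFP change, which favours medians of opposite sign. The wider spread of the GFP changes favours a larger GFP share, so neither is a separate finding. SKP2 lay just short of the 2-fold threshold, with a GFP change of 0.55 and a TFAP2B change of -0.35. With spike-in scaling both of its changes were positive, 2.16 and 1.00. Its difference between TFAP2B and GFP cells then went from -1.09 at day 2 to -2.25 at day 7, past the threshold. The change between days has no replicate, and the authors' table gave 612 such probes in place of 1813, while spike-in scaling turned the balance to 601 higher and 1431 lower.

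The E1A spike-in controls, RNAs of non-human sequence added at labelling, did not keep a constant level relative to the cells' RNA. Relative to the array's 75th percentile, the 6 controls of middle brightness were higher on the TFAP2B array than on the GFP array by 1.09 ± 0.057 (SD over the 6 controls) at day 2, a 2.13-fold difference, and by 1.36 ± 0.14 at day 7, or 2.57-fold. From day 2 to day 7 they changed by -1.34 in TFAP2B cells and -1.61 in GFP cells. Every difference above is therefore one in relative abundance.

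**Figure D3:**
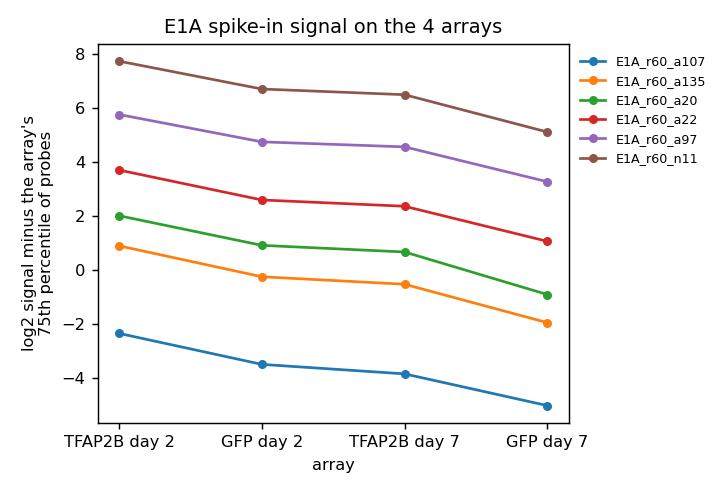
Log2 signal of the 6 E1A spike-in controls of middle brightness (lines) relative to the 75th percentile of the probes on the same array (vertical axis), for the 4 arrays in slide order (horizontal axis). All 6 were highest on the TFAP2B day 2 array and lowest on the GFP day 7 array, with mean signals of 7176 and 1580 before scaling.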

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

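Tests of the spike-in controls, of a deviating array and of a difference between the cell populations were chosen after the results were seen. The other tests were set before their results were computed.

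The spike-in controls enter the comparisons only where arrays were scaled to them. They were higher relative to the cells' RNA on both TFAP2B arrays, by 1.09 at day 2 and 1.36 at day 7 on the log2 scale. Compression of bright spots is argued against, since the dimmest of the middle controls shifted by at least 1.15 at both days. The 2 controls brightest on the GFP day 7 array shifted by less, 0.35 and 0.60 at day 2. On the TFAP2B day 2 array E1A_r60_n11 (7.74), counted as middle, was brighter than E1A_r60_n9 (7.65), counted as brightest. E1A_r60_n11 shifted by 1.03 at day 2. Unequal spike-in amounts would shift the middle controls alike, and the SD over these was 0.057 at day 2. A lower yield of labelled RNA in TFAP2B cells predicts the same, while the change between days within a transgene reached -1.61, larger than the shift between transgenes. Unequal amounts and a lower yield cannot be told apart because the signal fell in slide order and each array had its own labelling.

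More probes changed from day 2 to day 7 in GFP cells than in TFAP2B cells. Among probes above background on all 4 arrays, 13944 were brighter than the median. Of these, 674 changed in GFP cells and 97 in TFAP2B cells, a ratio of 6.95, which argues against noise of dim probes. Blocks of neighbouring spots took 1.14% of the variance of the GFP difference, above the at most 0.654% after shuffling, so a positional part was present. Its small size argues against position on the array as the main source. The lowest ratio over 4 other normalizations was 2.65, which argues against scaling, and although spike-in scaling gave 1.08, with 27085 and 25097 probes past 2-fold, a shift common to all probes leaves the SDs of 0.54 and 0.39 as they are. The GFP day 7 array correlated at 0.982 with the GFP day 2 array and at 0.977 with the TFAP2B day 7 array. With the TFAP2B day 2 array it correlated at 0.971, the lowest of any pair. The GFP day 2 array also correlated at 0.977 with the TFAP2B day 7 array. A single deviating GFP array cannot be told apart from a larger change in the GFP cells, which may be a candidate explanation, because each time has 1 array. The day 7 differences, the GFP changes over time and the changes of the difference between days all use the GFP day 7 array. These results are therefore not independent of each other.

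The differences between TFAP2B and GFP cells at day 2 recurred at day 7. The correlation among the brighter 13944 probes was 0.610, which decides nothing about noise of dim probes, because the days share no array and such noise could only lower it. Position on the array is argued against by a correlation of 0.586 after block means were removed. Of the variation between arrays, 56.4% went with the transgene. An effect of TFAP2B is a hypothesis that would give this. It cannot be told apart from another difference between the TFAP2B and GFP cell populations, because each transgene has 1 population in the labels. Nor can it be told apart from an effect of slide position or labelling, because the TFAP2B array came before the GFP array at both days.

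Differences of opposite sign at the 2 days, none of them tested, were found for SKP2 (0.0040 at day 2 and -0.89 at day 7), the full-length TERT probe (-0.39 and 0.067) and WDR33 (-0.11 and 0.086). They were lost with the authors' table, where SKP2 was -0.0068 at day 2 and the TERT probe -0.015 and WDR33 -0.00084 at day 7, and with median scaling, where these were -0.023, -0.028 and -0.0081. With quantile normalization SKP2 and the TERT probe were again negative at both days and WDR33 was 0 at day 7. With normexp all 3 had opposite signs at the 2 days, with WDR33 then positive at day 2 (0.033) and negative at day 7 (-0.0012). At the 2-fold threshold 11 probes were higher at day 2 and lower at day 7, and 30 were lower at day 2 and higher at day 7, also untested.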

How the results depend on the processing

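Normexp, spike-in scaling and the comparison of days in TFAP2B cells were added after the data were examined. Of 50 alternatives for the main results 23 stayed within 1.5 times the count, or within a narrow interval of the correlation, and 27 moved. Around the correlation of 0.584, a value of 0.589 counted as within the interval and 0.593 as moved. Since probes are not independent replicates, these labels for the correlation do not measure its spread. Quantile normalization moved none. The authors' table gave 1306 probes at day 2, 1577 at day 7, 893 over time in GFP cells, 331 over time in TFAP2B cells, 612 whose difference changed between days, and a correlation of 0.593. Normexp gave 1222, 1608, 1009, 245 (78 higher and 167 lower, against 574 and 386), 723 and 0.609, and 3054 in limma. No filter on dim probes gave 4625, 5519, 4755, 2793, 5791 and 0.436. Only probes above background on both arrays left 584 over time in TFAP2B cells, by construction. Median scaling gave 3166 in limma (1682 higher, 1484 lower) and split the TFAP2B time counts 428 higher to 486 lower. The limma fit pairs the transgenes by day, and dropping the day block gave 814. Other settings gave 1625 to 2490 in limma. Spike-in scaling shifted all probes by a median of -1.07 at day 2, -1.39 at day 7, 1.67 over time in GFP cells and 1.34 in TFAP2B cells. It gave 18028 (338 higher, 17690 lower), 24163 (222 and 23941), 27085 (27052 and 33), 25097 (25082 and 15) and, in limma, 27245 (446 and 26799). Probes whose difference changed between days then split 601 to 1431, against 1313 to 500. The limma differences of CTTN (-1.13), PSMB5 (-0.82) and UHRF1 (-0.87) turned negative and were called, as were those of SKP2 (-1.67), the full-length TERT probe (-1.39) and WDR33 (-1.23), already negative, and the time differences of UHRF1 (0.38 in GFP cells, 0.32 in TFAP2B cells) turned positive. Apart from that shift and the filters, the cause was not tested. Without spike-in scaling, 188 of 208 alternative values of named genes and probes had the sign of the main value. Averaging over probes of a gene and the gene list medians were not run, for want of gene names. Signal over background limits the comparisons to about 29463 to 30292 probes per array.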

Other observations

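The array also held 6 probes whose IDs begin with NNG or NNG1 and name exons or a fusion. Of these, 5 were above background on all 4 arrays, and their differences between TFAP2B and GFP cells were at most 0.39 in size. The exon 5 probe had signals of 144585 to 165024, and the exon 2 probe was flagged above background on the GFP arrays alone. Its signal at day 7 was nevertheless 26.0 in TFAP2B cells and 23.0 in GFP cells. Its bounds were 0 at both days, so the flags show no difference in expression. What these names stand for is not given in the sources used here.

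Probes with UniGene-type IDs were above background on all 4 arrays in 57.1% of cases, against 64.8% of catalogue probes. Their shares with a 2-fold difference between TFAP2B and GFP cells were 8.42% and 7.82% at day 2, and 11.8% and 9.96% at day 7. The 27889 probes above background on all 4 arrays were ranked by brightness into 4 equal groups, which leaves out dimmer probes. The brightest group had 104 higher and 47 lower at day 2 and 247 higher and 81 lower at day 7. In the dimmest group there were 345 and 247 at day 2 and 495 and 259 at day 7. The correlation of the day 2 and day 7 differences was 0.47 in the dimmest group and 0.59 to 0.66 in the others.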
